A study of Rattus norvegicus with 8 samples.

How the data were processed

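RNA from the hypothalamic paraventricular node of Sprague-Dawley rats at postnatal day 15 was measured on Agilent 2-colour arrays. The 8 samples, 4 from males and 4 from females, each occupied 1 dye channel, Cy3 or Cy5. Per the labels, the dams and the pups had received saline as controls and the 4 samples of each sex were biological replicates. The labels do not say from which litter each sample came. Dye, slide and array of each sample were read from the labels. Replicates 1 and 3 of each sex were labelled with Cy3 and replicates 2 and 4 with Cy5. The 4 male samples lay on 3 arrays of 2 slides, with male replicates 3 and 4 sharing array 3. The 4 female samples lay on 2 arrays of another slide, with female replicates 1 and 2 sharing array 4 and female replicates 3 and 4 sharing array 5. No array and no slide held both sexes.

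The authors deposited 1 table of log2 values, with a feature number for each row and a column for each sample. Intensities were extracted with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The treatment of background, the filter on spots and the scaling statistic were not given in the sources used here. The log base was settled from the values. Raised to base 2, 100% of the values of each sample were a whole multiple of a constant of that sample, within 0.1 of a whole number. Base e gave at most 20.8% and base 10 at most 20.3%, but the constant was refined for base 2 only. The log base thus rests on the 100% at base 2 and not on that contrast. The deposited values are therefore whole-number intensities divided by 1 number per sample and then log2-transformed, with no intensity-dependent step after the whole numbers. The divisors ran from 1338.5 in female replicate 3 to 2822 in male replicate 4. Which features set them is not stated. The reason why a cell was empty is not stated either, so empty cells were treated as missing and no floor was set.

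The table listed 44254 features numbered up to 45220. The other 966 numbers were not analysed here. Of the features listed, 1377 were empty in every sample, 42877 had a value in at least 1 sample and 32987 had a value in all 8. A feature was tested where it had at least 2 values in each sex and where sex and dye could both be estimated, a rule set after the empty cells were seen. This left 41853 features. No filter on dim features was applied.

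Each sample was centred on its median over the 32987 complete features. The log2 values were fitted with limma 3.58.1 in R 4.3.3 with sex and dye as fixed effects and the array as a random block (duplicateCorrelation), followed by eBayes with an intensity trend. The correlation between samples of the same array was estimated at 0.734. The contrast was female minus male, and the threshold was a Benjamini-Hochberg adjusted p of 0.05 over the features tested. Variability was compared as the SD of the residuals of the sex and dye fit within each sex, summarised as the median over complete features of log2(female SD / male SD). Its two-sided exact permutation test regrouped the residuals of this fit over the 35 splits of the 8 samples, without a new fit per split. Exact means only that every split was run. The residuals are not exchangeable, since the fit builds in a correlation of -0.6 between samples of the same sex and dye. Between other samples it builds in -0.2 or 0.2. Features whose sexes did not overlap were counted among complete features. Features with a value in every sample of a sex and in none of the other were counted among all features listed. Intervals are 95% confidence intervals from the moderated fit. For arrays, the number of samples limits the precision, and here it is limited further by the 5 arrays and 3 slides on which they lay.

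The spot grid was inferred, since the table gives only feature numbers. The highest number, 45220, is 532 rows of 85 spots, and the correlation between features a fixed distance apart peaked at 85 or at a multiple of it. Row and column below follow from this row length and are not stated by the authors. As an alternative chosen after seeing the data, a position trend was removed from each sample, taken as the median deviation from the feature means over a window of 11 by 11 spots without the spot itself. The removal was partial, since the female minus male difference still correlated by 0.253 between spots of neighbouring rows after it.

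The calculations were tested on simulated data of the same 41853 features and the same design, built from the main fit. For each of 2 sizes, 100 complete features were changed. Of these, 70% of the 4-fold and 9% of the 2-fold changes passed the adjusted threshold, with 4 false calls. With no effect simulated, 2 features were called and 4.94% lay below an unadjusted p of 0.05. This simulation held a single array correlation, no position trend and no slide effect. Its recovery and false calls may therefore not hold for the measured data. The ratio of SDs was tested on separate simulated data of independent samples, with no array effect. A ratio set to 0.585 on the log2 scale came out as 0.415 with the shared dye fit, and as 0.599 with dye removed within each sex. The shared dye fit thus understated the ratio for independent samples, and its behaviour with samples that share an array was not tested.

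The feature numbers were not paired with genes in the table, and the reference table used here pairs gene symbols with locus tags and RefSeq accessions only. The unit of every test was therefore the feature. The comparisons fixed before the data were examined that need gene symbols were not run. These were the lists of synaptic, neuropeptide, sex-linked and cell type marker genes, the share of genes on the sex chromosomes, the genes to be named whatever their values, and the alternatives on probes of the same gene. The rule for named genes was to take those past the threshold with the largest fold in each direction, filled up with those of smallest unadjusted p where too few passed. It was applied to features, and kept to the 2 features of smallest p in each direction because they carry no gene name. A sample's label was not checked against a sex-linked gene for the same reason. Alternatives covered the scaling (as deposited, quantile, cyclic loess), the dimmest 25% of features, the array, slide and replicate blocks, the dye term, each dye alone, the variance model, the threshold, leaving out each sample in turn, and 6 further settings chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.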

Results

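The paraventricular node is a hypothalamic cell group whose neurons release neuropeptide hormones, among them oxytocin and vasopressin, and regulate the pituitary. Its transcriptome was measured at postnatal day 15 in 4 male and 4 female saline-treated control rats, in order to compare gene expression between the sexes, with synaptic genes as the stated interest. Values were deposited for 44254 array features, of which 42877 had a value in at least 1 sample. The share of these that was empty in a sample was lowest in male replicate 1, at 0.121%, and highest in female replicate 4, at 18.6%. In males it was 1.10% in replicate 2, 0.448% in replicate 3 and 6.76% in replicate 4. In females it was 1.20% in replicate 1, 10.2% in replicate 2 and 4.06% in replicate 3. The deposited log2 values ran from -5.82 to 8.39, and sample medians over the 32987 complete features lay between -0.47 and -0.56. Across features, which are not independent replicates, Pearson's r between samples was 0.943 to 0.989 within a sex and 0.943 to 0.980 between the sexes.

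The first comparison asked which features differed in level between females and males. None of the 41853 features tested passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.611. An ordinary test of each feature in the same fit, without limma's moderation, also called 0 features, with a smallest adjusted p of 0.216. At an unadjusted p under 0.05, limma counted 2737 features, or 6.54% of those tested, where 2093 were expected by chance. Of these, 1050 were higher in females and 1687 were higher in males. The estimate was higher in females for 18746 features and higher in males for 23107. Leaving out the dye term gave 10 features past the adjusted threshold, and leaving out female replicate 3 gave 2. The unadjusted count ranged from 1284, after partial removal of the trend with position on the array, to 6356, with replicate number as a block. That block replaced the array block, so samples of the same array were treated as independent.

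**Figure D1:**
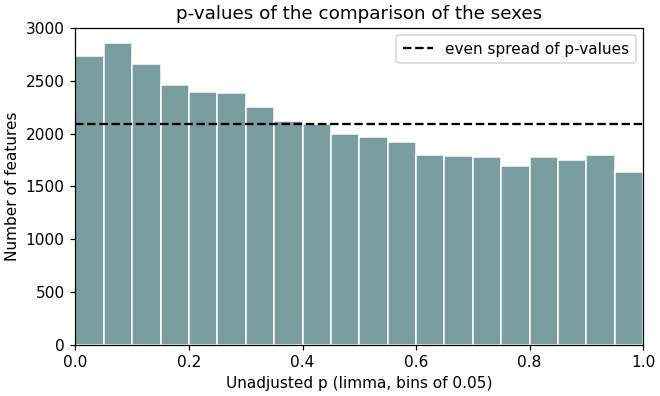
Unadjusted p-values of the comparison of the sexes in limma for the 41853 features, in bins 0.05 wide on the horizontal axis, with the number of features per bin on the vertical axis. The dashed line is the 2093 features per bin that an even spread would give. The lowest bin holds 2737, fewer than the 2860 of the next bin, so the smallest p-values form no peak.

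The precision of these estimates set what could be detected. The median standard error of a sex difference was 0.32 on the log2 scale, and the median 95% confidence interval reached 0.72 either side of the estimate, which is 1.64-fold. The median absolute difference was 0.27. An estimate beyond 2-fold was found for 1080 features, 2.58% of those tested. The 95% confidence interval lay wholly within 4-fold for 39039 features (93.3%) and wholly within 2-fold for 19623 (46.9%). For the remaining features the fit did not exclude a 2-fold difference. The intervals hold no term for the slide, and no slide held both sexes. An interval within 2-fold therefore covers sex and slide together and does not by itself exclude a 2-fold sex difference.

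The 2 features of smallest p in each direction did not pass the threshold, each with an adjusted p of 0.611 in limma. Feature 18185 was estimated higher in females by 4.67 on the log2 scale (SE 0.511, 95% confidence interval 3.47 to 5.87). Its mean was 1.93 ± 1.33 (SD, n = 2) in females and -2.49 ± 0.264 (SD, n = 3) in males, and both female values came from array 4. Feature 8752 was estimated higher in females by 4.03 (SE 0.536, 95% confidence interval 2.80 to 5.26). Its mean was 0.976 ± 1.31 (SD, n = 2) in females, both on array 5, and -3.14 ± 0.841 (SD, n = 4) in males. The spots that touch these features were also brighter than the male mean of the same spots, by a median of 3.55 on array 4 around feature 18185 and 0.863 on array 5 around feature 8752, on the log2 scale. Feature 2944 was estimated lower in females, at -1.20 (SE 0.189, 95% confidence interval -1.62 to -0.78). Its mean was 0.271 ± 0.216 (SD, n = 4) in females and 1.49 ± 0.132 (SD, n = 4) in males. Feature 14371 was estimated lower in females, at -1.25 (SE 0.201, 95% confidence interval -1.69 to -0.80). Its mean was 0.0714 ± 0.152 (SD, n = 4) in females and 1.34 ± 0.354 (SD, n = 4) in males. For both of these, 4 of 4 females lay below every male. Their touching spots were also dimmer than the male mean of the same spots. The median difference was -0.816 on array 4 and -0.538 on array 5 around feature 2944. Around feature 14371 it was -0.482 on array 4 and -0.845 on array 5. Among all neighbourhoods of array 4 these medians lay at percentile 4.08 for feature 2944 and 8.04 for feature 14371. Among those of array 5 they lay at percentile 15.3 and 8.91. After partial removal of the trend with position, the differences were 4.73 for feature 18185, 3.52 for feature 8752, -0.64 for feature 2944 and -0.84 for feature 14371.

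**Figure D2:**
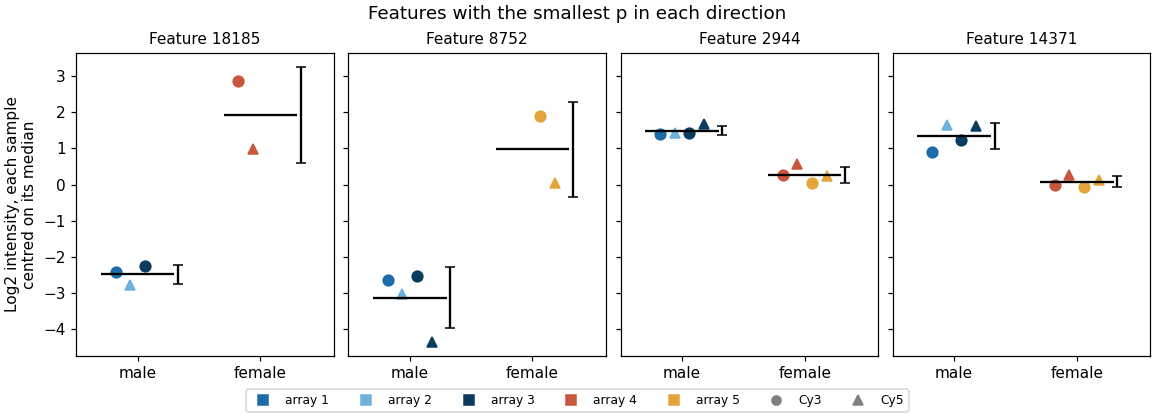
Log2 intensity, centred on each sample's median, of the 2 features of smallest p in each direction, with a point per sample coloured by array and shaped by dye, the horizontal bar at the mean of each sex and the whisker at ± 1 SD. Females have values on array 4 only for feature 18185 and on array 5 only for feature 8752, while the 4 females lie below the 4 males for features 2944 and 14371.

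Among the 32987 complete features, the values of the sexes did not overlap for 3313, or 10.04%. Chance would give 2.86%, or 942 features, if all samples were independent. Samples of a sex shared arrays, so this figure is not a chance level for the design used here. Females were higher in 1962 of the 3313 features and males in 1351. After partial removal of the trend with position, 1071 features (3.25%) did not overlap. A value in all 4 males and in no female was found for 40 features, and the reverse for 0. The median male level of these 40 features was -3.06 and the highest was -2.50, a level below which 29.0% of all measured features lay. No fold is given for them, since the reason for an empty cell is not stated.

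The variation among samples was divided between dye, sex and array. Over complete features, dye accounted for 30.0% of the variation and sex for 19.0%, on 1 degree of freedom each. The array beyond sex and dye accounted for 45.1% on 3 degrees of freedom. The share given for sex also holds any difference between the slide of the females and the slides of the males. The remaining 5.87%, on 2 degrees of freedom, lay between samples of an array after the dye was removed. Samples of the same sex and dye on different arrays differed by a median absolute log2 difference of 0.359 between female replicates 1 and 3 and 0.385 between female replicates 2 and 4. The corresponding differences were 0.127 between male replicates 1 and 3 and 0.277 between male replicates 2 and 4. No array or slide held samples of both sexes. Females all lay on a slide of their own, so a comparison of the sexes within a slide was not possible, and with the slide as a random block the unadjusted count was 2354.

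The difference between the sexes followed the position of the spot on the array. The correlation of the female minus male difference between spots of neighbouring rows was 0.603 across features, while the highest absolute value in 1000 shuffles of the features was 0.0223. It was still 0.253 after the position trend was removed, so the removal was partial. The difference between the 2 female arrays, which involves no sex difference, had a correlation of 0.615. Between the 2 dyes of an array, that is, between 2 animals of a sex measured on the same spots, it was 0.140 on array 4, 0.175 on array 5 and 0.0777 on array 3. Between samples of the same sex and dye on different arrays it was 0.607 and 0.569 in the 2 female pairs. In the male pairs it was 0.491 on arrays of a slide and 0.203 on arrays of different slides. Along the feature numbers, the median female minus male difference went from -0.34 among features 13567 to 15827 to 0.31 among features 38439 to 40695. The mean level over all 8 samples had a correlation between neighbouring rows of 0.0292.

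**Figure D3:**
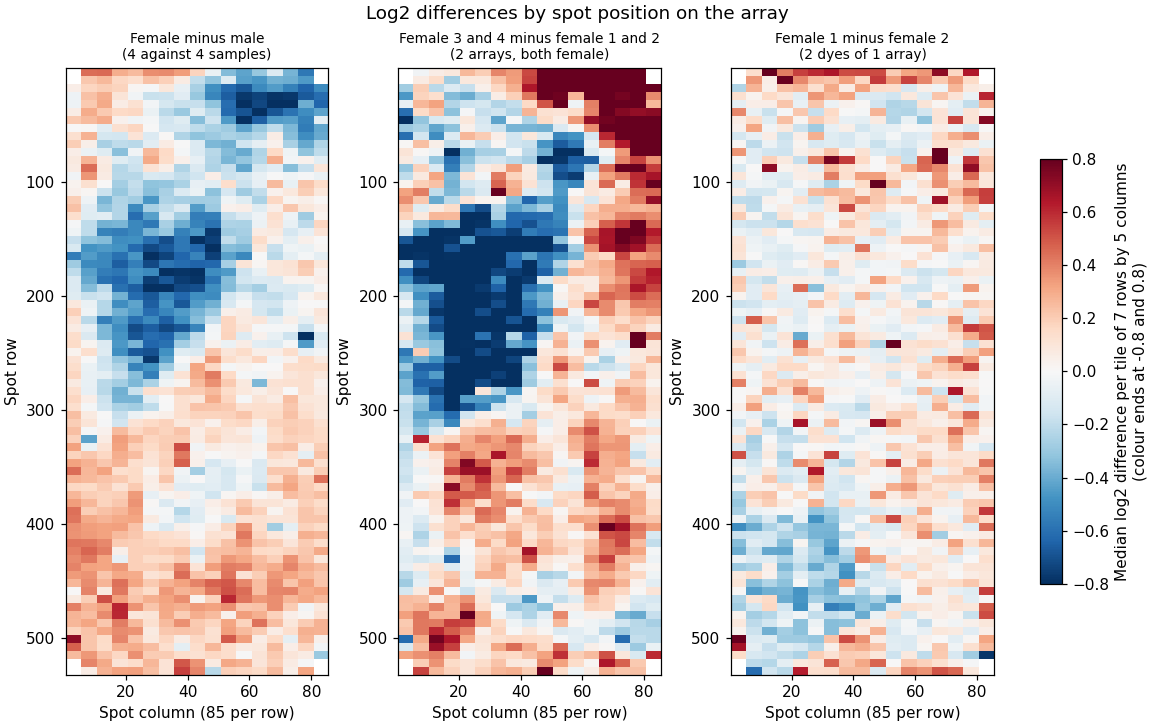
Median log2 difference per tile of 7 rows by 5 columns of the inferred spot grid, for females minus males, for array 5 minus array 4 (both female) and for female replicate 1 minus female replicate 2 (the 2 dyes of array 4), with the colour scale ending at -0.8 and 0.8. Broad patches appear in the first 2 maps, with correlations between neighbouring rows of 0.603 and 0.615, and the third has a correlation of 0.140.

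The second comparison asked whether expression varied more among the animals of a sex. The SD within a sex, after removal of dye, had a median over features of 0.258 in females and 0.178 in males (n = 4 each). The median log2 ratio of the SDs was 0.45 (1.37-fold), and 64.1% of features had the larger SD in females. In the exact permutation test, two-sided, p was 0.0571, with 2 of the 35 splits as large and a smallest possible p of 0.0286. These splits treat samples that share an array as independent, and the 3 splits that keep arrays whole are too few for a p under 0.05. With dye removed within each sex the ratio was 0.587 (exact permutation p = 0.0286). That p decides nothing, since same-dye samples of a sex then have equal and opposite residuals. Splits that part such samples shrink the ratio by construction. After partial removal of the trend with position the ratio was 0.18 (exact permutation p = 0.343), and without the dimmest 25% of complete features it was 0.71 (exact permutation p = 0.0286). Leaving out a sample moved it between 0.24 without female replicate 4 and 1.03 without male replicate 2.

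Whether synaptic genes, neuropeptide genes or sex-linked genes differed between the sexes was not analysed here, because the feature numbers were not paired with gene names. The coordination of genes across animals was not analysed either, since a correlation across 4 animals per sex would be imprecise.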

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

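The tests over all splits of the samples for the adjusted count, the unadjusted count and the features without overlap were fixed before their results were seen. The splits limited by dye or array, the splits after removal of the position trend, the splits for values in a single sex, and the tests on spot position, on spread and on neighbouring spots were chosen after.

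Among the 13 groups of 4 samples examined, of males or of females, 3 had a sample that stood apart, each time male replicate 4. Chance sets a sample apart in about 1 in 20 groups. The groups of females could not flag male replicate 4, so 3 of 13 is not its own rate. Feature 2944, 1 of the 3 flags, had itself been picked by its p. It had 2899 empty features, against 472 in the next male. Its scaling divisor was 2822, against 2036 in the next male. Its value of feature 2944 was 1.68, against 1.44 in the next male.

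Over all splits of the 8 samples, chance could not be excluded for the unadjusted count or for the features without overlap. For the adjusted threshold the splits decide nothing, since the real split gave 0 features, which all 34 of the 34 splits that could be fitted reach by construction, and the highest other gave 2. At an unadjusted p under 0.05, with the array correlation estimated on 5000 features, the real split gave 2795 features, 11 of the 34 splits gave as many and the highest other gave 6187. Features whose groups did not overlap numbered 3313 in the real split, 3 of the 35 splits gave as many, and the highest other, which parted Cy3 from Cy5, gave 4436. Among the 18 splits with 2 samples of each dye per group, the real split had the most features without overlap, with 1017 in the next, but 6 of the 18 gave as many at an unadjusted p under 0.05. Of the 3 splits that keep arrays whole, too few for a share under 0.05, the real one had the most at an unadjusted p under 0.05, 2795 against 1064 in the highest other. Removing the position trend left 1071 features without overlap, and 10 of the 35 splits then gave as many, the highest being 6909 in the split that parted the dyes. Of the 18 dye-balanced splits, 2 then gave as many, with 1102 in the highest other. Of the 3 splits that keep arrays whole, the highest other then gave 838. For features with a value in all samples of a group and none of the other, the real split gave 40, 3 of the 35 splits gave as many and the highest other gave 220.

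The dependence of the sex difference on spot position is the first pattern weighed. Intensity-dependent scaling left in the deposited values is argued against by a correlation between neighbouring rows of 0.618 after cyclic loess, and a layout that places features of like level side by side by the correlation of the mean level, 0.0292. Uneven hybridisation or scanning of single arrays is a candidate explanation, since the difference between the 2 female arrays was correlated by 0.615. Single samples of the same dye on those arrays gave 0.607 and 0.569, against at most 0.175 for the 2 dyes of an array, while the male pairs on different arrays gave 0.491 and 0.203, the latter close to the values within an array. A sex difference in the animals stays open beneath this trend, because no array held both sexes.

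The second pattern is the larger spread within females, a median log2 ratio of SDs of 0.45 that did not pass its exact permutation test (p = 0.0571). With dye removed within each sex it was 0.587 (exact permutation p = 0.0286), but these splits treat samples of an array as independent. That p also decides nothing, since splits that part same-dye samples of a sex shrink the ratio by construction. More dim spots in females are argued against, since the ratio was 0.709 without the dimmest 25% of complete features, while empty spots were not tested. Different position trends on the 2 female arrays may account for much of it, since the ratio was 0.182 once the position trend was removed. Sex, litter and dissection of the female animals cannot be told apart from the array, because each female array held animals of its own. Residuals of samples that shared an array correlated across features by 0.6999 for female replicates 1 and 2, 0.703 for female replicates 3 and 4 and 0.165 for male replicates 3 and 4, where the fit builds in -0.2.

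The third pattern is the pair of features estimated highest in females, 18185 and 8752, each with female values on 1 array only. A local mark on that array is a candidate explanation, since the median excess of the touching spots lay at the percentile 99.99 of all neighbourhoods of array 4 for feature 18185 and at the percentile 99.3 of array 5 for feature 8752. The 2 features called without female replicate 3 lay close to feature 18185, at 2 rows in the same column and at 1 column in the same row. In female replicates 1 and 2, on array 4, the first of them read 6.598 and 4.563 and the second 4.714 and 3.096. Female replicate 3, the only female value from array 5, read -3.03 and -3.44, within the male range of each feature. The excess of these 2 features was thus seen on array 4 only. Both pass only without female replicate 3, so its low value is tied to how they were picked and does not by itself exclude a sex difference. For features 18185 and 8752, a sex difference could not be tested apart from the array.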

How the results depend on the processing

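The removal of the position trend, alone or without the array block, the restriction to complete features, the array means, the dimmest 25% of complete features and the removal of dye within each sex were chosen after seeing the data. The count past the adjusted threshold was 0 in 22 of its 25 alternatives. It was 10 with no dye term (1 higher in females and 9 in males, adjusted p 0.0426 to 0.0439), 1925 with an unadjusted p under 0.05 and at least 1.5-fold, and 0 to 2 on leaving out a sample, with 2 only without female replicate 3 (adjusted p 0.0281 and 0.0411). The smallest adjusted p of a setting ranged from 0.0281 to 0.944. With no dye term, features 18185 and 2944 were among those called. The count at an unadjusted p under 0.05, 2737, became 4769 with quantile normalization, 1284 with the position trend removed, 6257 with no array block, 5241 with no dye term and 1714 with Cy5 samples only, where 33145 features were tested. On leaving out a sample it ranged from 1334 without male replicate 1 to 3116 without female replicate 1. With the replicate block in place of the array block it was 6356, with 0 adjusted calls. The replicate numbers were not taken to pair the samples, since the deviations of same-numbered samples from their sex means, which share a dye, correlated by 0.303, -0.0149, 0.420 and 0.468 for numbers 1 to 4, not all above 0.1. Within a dye, the male and female differences between replicate numbers correlated by -0.0287 for Cy3 and -0.0390 for Cy5. With dye removed in the joint fit same-numbered samples gave -0.191 to 0.000856 and 0 samples correlated best with their own number, but that fit builds in -0.2. The 3313 features without overlap became 1071 with the position trend removed and stayed within 1.5 times in the other 4 alternatives. The log2 ratio of SDs, 0.45, passed its exact permutation test (p = 0.0286, the smallest possible) at 0.557 without the dimmest 25% of all features (30303 complete features left), at 0.709 without the dimmest 25% of complete features and at 0.587 with dye removed within each sex. These p-values treat samples of the same array as independent, and the 3 splits that keep arrays whole cannot give one under 0.05. The p with dye removed within each sex decides nothing, since splits that part same-dye samples of a sex then shrink the ratio by construction. On leaving out a sample the ratio ranged from 0.235 to 1.03, and its p was 0.0286 without male replicate 1, 2 or 4. The log2 ratio of SDs and the 4 named features kept their direction in the alternatives where they were estimated. These numbered 17 for feature 18185, 18 for feature 8752 and 24 each for features 2944 and 14371. The direction of the counts was not followed across the alternatives. The causes of these shifts were not tested, except that fewer features were tested with Cy5 samples only. The alternatives on probes of a gene and those of gene lists, synaptic genes, genes outside the sex-linked lists and sex chromosomes were not run, since they need gene names. Signal over background was not analysed here.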

Other observations

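Over the complete features, the first 3 principal components of the samples held 37.1%, 31.5% and 15.8% of the variance. On the first component the 4 Cy3 samples lay between -73.4 and -28.0 and the 4 Cy5 samples between -0.290 and 82.4. On the second, female replicates 3 and 4, which shared array 5, lay at -59.7 and -88.5, while the other 6 samples lay between -5.46 and 50.5. On the third, the 4 females lay between -51.0 and -5.68 and the 4 males between 24.1 and 32.8.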
